A study of Mus musculus with 22 samples.

How the data were processed

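Total RNA of 22 cultures of Rex1GFPd2 mouse ES cells was labelled with biotin by a 3′ in vitro transcription kit and hybridised to Affymetrix mouse expression arrays, 1 sample per array and 1 colour, per the labels' protocols. The submitters' processing notes name RMA (robust multi-array average) as the tool that made the deposited values; its version and software are not given in the sources used here. The deposited values are taken as log2 expression per probe set, from the name of the tool and from their range of 2.09 to 14.91. RMA in its usual form corrects background, quantile-normalises the arrays and summarises the probes of a probe set by median polish; this makes the distributions of the arrays alike, so a change of total RNA per cell cannot be seen. Values were rounded to 2 decimals. RMA gives no detection call, and log2 differences against dim probe sets are compressed by background, so the fold of a gene that is dim in 1 arm understates its change by an unknown amount. No scan date or array batch was used here, so a batch that follows the arms cannot be told apart from them.

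The table holds 45101 probe sets with no missing value. The platform annotation gives 1 gene symbol for 34945 of them and several for 932; 9160 were not listed, with the 64 control probe sets left out of that count. The Entrez identifiers of 34741 probe sets were found in the RefSeq gene table, and no symbol needed an update. Probe sets with several symbols or none were left out of the gene tests and counted apart. Each of 18193 genes was represented by its probe set with the highest mean over all arrays; 9010 genes had several. Among genes named in the text, another probe set was called in the opposite direction for Malat1, Klf5 and Pax6 with CHIR and for Acta2, Tnfrsf19, Pax6 and Pdk1 between YAP/TAZ siRNA and 2i control.

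A linear model with 1 mean for each of the 6 groups of medium and siRNA was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes; 16 residual and 3.1 prior degrees of freedom). Arms were compared as the average of their siRNA groups, each siRNA with equal weight. Genes were called at a Benjamini-Hochberg adjusted p of 0.05, and a second count took those with an absolute log2 difference of at least 1. Errors of differences are standard errors of the model, and errors of arm means are SDs over arrays. Gene lists were tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the 24 lists in each comparison. The lists were naive, general, and formative and primed pluripotency, Wnt/beta-catenin targets, Wnt pathway components, YAP/TAZ-TEAD targets, Hippo pathway components, primitive streak and mesendoderm, neural, primitive endoderm, trophoblast, two-cell-like state, fibroblast (feeder cells), ERK targets, LIF/STAT3 targets, interferon response, p53 targets, G2/M, S phase, integrated stress and unfolded protein response, glycolysis, cholesterol synthesis, actin cytoskeleton and SRF targets, and housekeeping genes. Measures of array quality were compared between arms with two-sided exact permutation tests. The overlap of responses was set against 100 simulated pairs of unchanged groups sharing the control arrays, against independent lists, and against fits with the controls split by siRNA. On simulated data with 200 changed genes, the test recovered 98.5%, 100% and 97% of genes changed by 0.5 on the log2 scale for CHIR, for YAP/TAZ siRNA and for YAP/TAZ siRNA against 2i, and 100% of those changed by 1. These fits also made 12, 18 and 23 false calls, in each case more than 5% of the calls, and the fits for siRNAs of one kind made 14, 15 and 16.

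Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Named were Yap1 and Wwtr1; the 10 highest and 10 lowest log2 differences for CHIR and for YAP/TAZ siRNA, and 5 of each for YAP/TAZ siRNA against 2i, among called genes with an arm mean at or above the median of all genes (6.62) and with siRNA group means that did not overlap; 10 genes called in both main comparisons in the same direction and up to 5 in opposite directions with the largest smaller change, at the same level; up to 4 called members of each list with the largest change per comparison; and any member of the naive pluripotency, Wnt/beta-catenin and YAP/TAZ-TEAD lists. Genes with predicted names were passed over, 3 in all. Alternatives covered the rule for several probe sets, cross-hybridising probe sets, dim genes, a further normalization, the variance model, array weights, the arrays in the fit, pooling or random blocking of siRNAs (statmod 1.5.0), the replicate block, each array left out, each siRNA alone, and a stricter call. An RNA quality covariate was added after the data were seen. Figures were drawn with matplotlib 3.10.9 and tables joined with pandas 2.3.3 in Python 3.11.15.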

Results

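Gene expression was measured in mouse embryonic stem (ES) cells of the Rex1GFPd2 line, which carry a destabilised green fluorescent protein at the Rex1 (Zfp42) locus. The 2i medium holds PD0325901 (PD), an inhibitor of the kinase MEK, and CHIR99021 (CHIR), an inhibitor of the kinase GSK3, which marks beta-catenin for destruction. Cells were transfected with 1 of 2 control siRNAs or 1 of 2 siRNA mixes against YAP and TAZ (genes Yap1 and Wwtr1), the transcriptional coactivators of the Hippo pathway. They were either kept in 2i or moved after 24 hours to medium with PD alone, and were harvested 72 hours after transfection. Control siRNA cells in 2i gave 7 arrays, control siRNA cells in PD-only medium 7 arrays, and YAP/TAZ siRNA cells in PD-only medium 8 arrays. Control siRNA 1 had 4 arrays per medium, control siRNA 2 had 3, and each YAP/TAZ mix had 4. The title of the series places YAP and TAZ in the complex that destroys beta-catenin. The comparisons ask how gene expression differs with and without CHIR, and how far loss of YAP and TAZ resembles its presence in medium without it. CHIR was withdrawn and not added, so a rise or fall with CHIR means a higher or lower value in 2i than in PD-only control. A change of medium after 24 hours is given for the PD-only arms and not for 2i. Its effect cannot be told apart from that of losing CHIR. The labels call each array a biological replicate, without saying whether replicates came from separate days. The number of arrays limits the precision. The p-values of limma set each difference against the spread between arrays of the same group, and may not cover variation between experiments.

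The medians of the 22 arrays were 5.52 ± 0.010 in 2i control (SD, n = 7), 5.55 ± 0.005 in PD-only control (n = 7) and 5.52 ± 0.005 with YAP/TAZ siRNA (n = 8), all on the log2 scale. The median was lower than in PD-only control by 0.023 in 2i control and by 0.030 with YAP/TAZ siRNA (exact permutation p = 0.00175 and p = 0.000155; 0.00446 and 0.00093 after Benjamini-Hochberg adjustment over 24 tests of array quality). The interquartile range was lower by 0.064 and 0.070 (exact permutation p = 0.00583 and p = 0.0028; 0.0117 and 0.00611 after adjustment). No 2 arrays held identical values, and within an arm the correlation over genes between arrays was at least 0.9977. The difference between the 3′ and 5′ control probe sets of Actb, which grows as RNA degrades, was lower in PD-only control (0.717 ± 0.035, n = 7) than in 2i control (0.966 ± 0.104, n = 7) by 0.249 and than with YAP/TAZ siRNA (0.975 ± 0.062, n = 8) by 0.258. Both differences passed a two-sided exact permutation test (p = 0.000583 and p = 0.000155, or 0.00175 and 0.00093 after adjustment). The Gapdh 3′ minus 5′ value was lower in PD-only control too, by 0.063 and 0.058 (exact permutation p = 0.000583 and 0.00186, or 0.00175 and 0.00446 after adjustment). The Gapdh 3′ minus middle value differed from PD-only control by -0.014 in 2i control and -0.032 with YAP/TAZ siRNA (exact permutation p = 0.409 and 0.0409, or 0.517 and 0.0654 after adjustment). The poly-A spike controls, added to the RNA before labelling, averaged 8.96 ± 0.15 in 2i control (n = 7), 8.52 ± 0.17 in PD-only control (n = 7) and 8.43 ± 0.12 with YAP/TAZ siRNA (n = 8). The 2i arm was higher than PD-only control by 0.440 (exact permutation p = 0.000583) and than YAP/TAZ siRNA by 0.533 (exact permutation p = 0.000155). The arms in PD-only medium differed by 0.092 (exact permutation p = 0.247).

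Both targeted genes were lower in every YAP/TAZ siRNA array than in any control array. Yap1 fell by 1.27 ± 0.03 (SE) on the log2 scale against PD-only control, to 41.4% of its control level, with limma's adjusted p = 2.61e-18. Wwtr1 fell by 1.04 ± 0.03, to 48.7% (adjusted p = 5.32e-17). The mixes left 42.1% and 40.8% of Yap1 and 47.9% and 49.6% of Wwtr1. All 5 probe sets of these genes fell, the dimmer Yap1 probe set by 0.64 ± 0.05. In 2i control cells Yap1 and Wwtr1 were also below PD-only control, with log2 differences of -0.15 ± 0.03 and -0.25 ± 0.03. With the Actb 3′ minus 5′ value as a covariate the Yap1 difference was -0.15 with adjusted p = 0.0578.

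**Figure D1:**
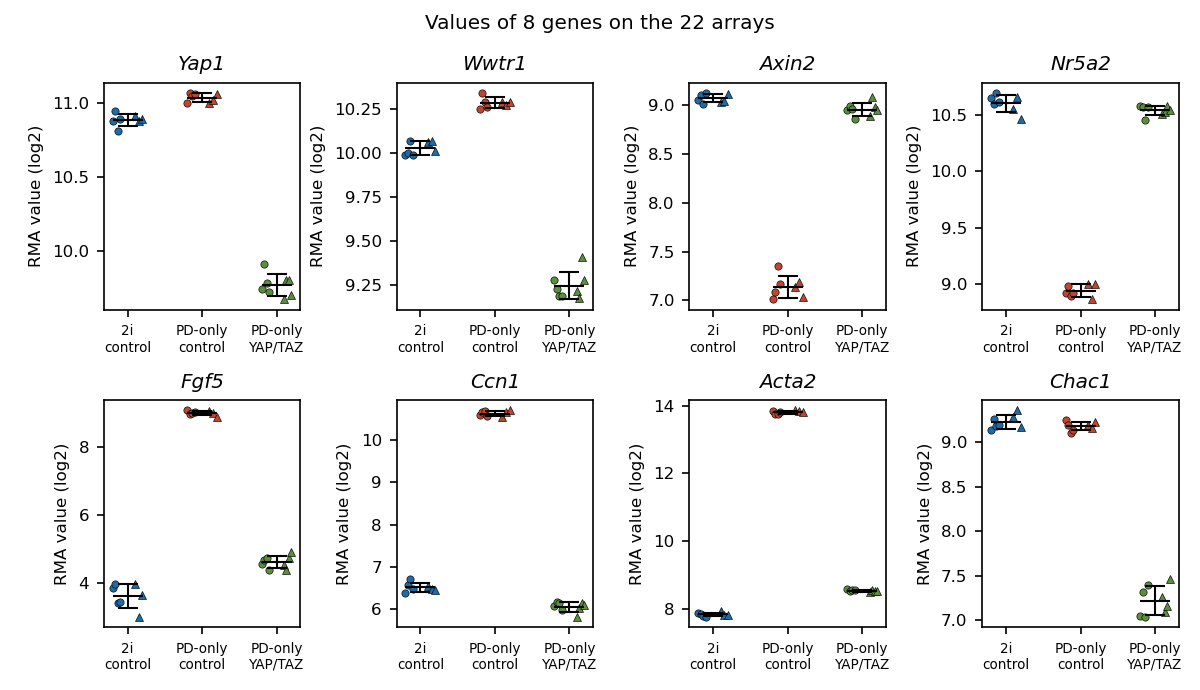
RMA values (log2) of 8 genes on the 22 arrays, by arm; circles are control siRNA 1 or YAP/TAZ mix 1, triangles control siRNA 2 or mix 2, and bars the mean ± SD of 7, 7 and 8 arrays. With YAP/TAZ siRNA, Axin2 and Nr5a2 are higher and Fgf5, Ccn1, Acta2 and Chac1 lower than in PD-only control; Fgf5 stays 1.01 above the 2i control level.

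The largest differences between the media lay at genes that were high in PD-only control and low in 2i. Among genes that met the naming rule, the lowest differences, 2i minus PD-only control, were Car4 (carbonic anhydrase 4; log2 -7.59 ± 0.07, 193-fold lower in 2i), Acta1 (skeletal actin; -7.17 ± 0.10), S100a6 (-6.98 ± 0.07), the simple-epithelium keratins Krt8 (-6.67 ± 0.03) and Krt18 (-6.04 ± 0.04), Prss23 (-6.41 ± 0.08), Tagln (transgelin; -6.33 ± 0.06), Acta2 (smooth muscle actin; -5.96 ± 0.03), Pmp22 (-5.73 ± 0.06) and Vgll3 (a TEAD cofactor; -5.66 ± 0.07). The highest were Trpm1 (a cation channel; 5.39 ± 0.04, 41.8-fold higher in 2i), the homeobox gene Nkx1-2 (5.36 ± 0.04), Ntn1 (netrin 1; 4.16 ± 0.04), Ccdc141 (4.03 ± 0.09), Cnpy1 (3.44 ± 0.08), Epp13 (3.39 ± 0.05), Btla (3.30 ± 0.10), Dnah8 (3.17 ± 0.03), Manba (3.16 ± 0.03) and Trh (3.15 ± 0.03). The adjusted p of these 20 genes ranged from 3.51e-30 to 1e-16 with 7 arrays per arm. Of 18193 genes, 10559 passed an adjusted p of 0.05, 5702 higher and 4857 lower in 2i; 1057 of them differed by 2-fold or more, 307 higher and 750 lower.

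Naive pluripotency genes rose with CHIR: 16 of 18 measured members were higher in 2i and none lower (adjusted p of the list = 1.25e-07). The transcription factors Nr5a2 (1.66 ± 0.03), Tfcp2l1 (1.58 ± 0.03) and Esrrb (1.03 ± 0.02) rose most. Klf2 rose by 0.90 ± 0.02, Nanog by 0.51 ± 0.02 and Zfp42 by 0.34 ± 0.03. Fbxo15 (-0.03 ± 0.02) and Sox15 (0.11 ± 0.07) did not pass the test. Among the 16, Klf4 and Gbx2 lost their calls with the Actb 3′ minus 5′ value as a covariate (limma's adjusted p = 0.294 and 0.424). Klf4, Klf5 and Gbx2 lost theirs with control siRNA 2 alone (adjusted p = 0.767, 0.234 and 0.136). Klf5 differed by 0.01 with the mean of all its probe sets (adjusted p = 0.756). Formative and primed genes fell, 9 of 12 lower and 3 higher (adjusted p = 0.000497), led by Fgf5, a marker of the post-implantation epiblast (-5.40 ± 0.12), Pou3f1 (-1.90 ± 0.04), Fgf15 (-1.86 ± 0.08) and Sall2 (-1.78 ± 0.08). General pluripotency genes went both ways, 5 of 11 higher and 6 lower (adjusted p = 0.953), with Pou5f1 (Oct4) at 0.43 ± 0.03, Sox2 at 0.36 ± 0.03 and Lin28a at -1.28 ± 0.13.

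Of 17 measured Wnt/beta-catenin targets, 10 were higher in 2i, 3 lower and 4 not called. The negative feedback gene Axin2 rose by 1.94 ± 0.05, Tnfrsf19 by 2.42 ± 0.03, Sp5 by 1.50 ± 0.07 and Cdx1 by 1.42 ± 0.07, and Notum by 1.08 ± 0.04. Dkk1, a secreted Wnt antagonist, fell by 4.08 ± 0.06 and Myc by 0.96 ± 0.05, and Lef1 did not pass the test (-0.02 ± 0.03). The list as a whole had an adjusted p = 0.0164, and adjusted p = 0.0642 with an estimated correlation. Among 18 Wnt pathway components, 6 rose, 5 fell and 7 did not pass (adjusted p = 0.96), with Porcn, which acylates Wnt proteins, at 1.93 ± 0.06 and Wls, which carries them to the surface, at -1.82 ± 0.04.

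YAP/TAZ-TEAD targets fell with CHIR: 16 of 22 were lower, 13 of them by 2-fold or more, and 2 were higher (median -1.40; adjusted p = 1.86e-09). F3 (tissue factor; -4.24 ± 0.05), Ccdc80 (-4.12 ± 0.07), Ccn1 (-4.10 ± 0.05), Ankrd1 (-3.80 ± 0.07), Tgfb2 (-3.68 ± 0.06), Axl (-2.92 ± 0.06) and Ccn2 (-2.89 ± 0.03) were among them. Of 15 Hippo pathway components, 4 rose and 7 fell (adjusted p = 0.104), the angiomotin Amot by 3.45 ± 0.04. All 16 actin cytoskeleton and serum response factor (SRF) genes fell, 12 by 2-fold or more (median -3.33; adjusted p = 3.44e-16), among them Anxa2 (-5.22 ± 0.04) and Myl9 (-5.21 ± 0.10). The Actb 3′ minus 5′ value was lower in the same PD-only control arm, by 0.249, and the poly-A spikes by 0.440, as given for array quality. The spikes set the 2i arm apart from both PD-only arms, which differed from each other by 0.092.

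Markers of other cell types also fell with CHIR. Fibroblast genes had 8 of 10 lower and none higher (adjusted p = 2.32e-05), with Col1a2 at -4.56 ± 0.08, Col1a1 at -4.01 ± 0.09 and Postn at -3.17 ± 0.06. Trophoblast genes had 7 of 12 lower and 2 higher (adjusted p = 0.000688); those that fell most were Krt8, Krt18, Krt7 (-4.57 ± 0.08) and Gata3 (-2.49 ± 0.06), of which Krt8 and Krt18 mark simple epithelia in general. Primitive endoderm genes had 8 of 14 lower and 2 higher (adjusted p = 0.00677), namely the basement membrane genes Col4a2 (-3.75 ± 0.05) and Col4a1 (-3.31 ± 0.04) and the endocytic adaptor Dab2 (-3.05 ± 0.10) among the lower ones. All 14 G2/M genes fell (median -0.52; adjusted p = 8.26e-09), most of all Cdc20 (-1.06 ± 0.03), with Aurka at -0.70 ± 0.04. Of 12 cholesterol synthesis genes 10 fell (adjusted p = 2.74e-05), among them Fdps (-0.93 ± 0.04), Hmgcs1 (-0.76 ± 0.03) and Idi1 (-0.67 ± 0.03). In all, 14 of 24 lists passed the threshold, and 9 with an estimated correlation. Neural genes (3 of 14 higher, 6 lower; median 0.00, mean -0.52), two-cell-like genes (4 of 5 higher), LIF/STAT3 targets (4 of 11 higher, 6 lower) and p53 targets (4 of 14 higher, 9 lower) were past it only with the preset correlation, with adjusted p = 0.0499, 0.0436, 0.0494 and 0.03, and adjusted p = 0.0678, 0.114, 0.16 and 0.0642 with an estimated correlation. Adjusted over the list alone, the counts of members higher and lower were those over all genes in every list of this comparison except ERK targets, where 7 rather than 6 were higher.

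YAP/TAZ siRNA in PD-only medium moved many of the genes that CHIR moved. Among genes that met the naming rule, the lowest differences, YAP/TAZ siRNA minus control, were Car4 (-6.38 ± 0.07, 83.5-fold lower), Prss23 (-6.36 ± 0.08), S100a6 (-5.90 ± 0.07), Acta1 (-5.86 ± 0.09), Krt8 (-5.80 ± 0.03), Ptgs2 (cyclooxygenase 2; -5.79 ± 0.10), Krt18 (-5.65 ± 0.04), Pmp22 (-5.53 ± 0.06), Thbs1 (thrombospondin 1; -5.52 ± 0.07) and Tagln (-5.31 ± 0.06). The highest were Nkx1-2 (5.60 ± 0.04, 48.6-fold higher), Trpm1 (4.91 ± 0.04), the embryonic globin Hbb-bh1 (3.72 ± 0.08), Ccdc141 (3.72 ± 0.09), Ntn1 (3.48 ± 0.04), Aurkc (3.26 ± 0.04), Btla (3.24 ± 0.10), Cdo1 (3.10 ± 0.04), Dmgdh (3.09 ± 0.07) and Dnah8 (3.03 ± 0.03). Their adjusted p ranged from 1.37e-28 to 6.66e-17 with 8 and 7 arrays. In all, 11250 genes passed an adjusted p of 0.05, 6463 higher and 4787 lower, and 1158 of them differed by 2-fold or more, 345 higher and 813 lower.

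The YAP/TAZ-TEAD targets fell with the siRNA, 17 of 22 lower, 12 of them by 2-fold or more, and 3 higher (median -1.67; adjusted p = 3.06e-09). Ccn1 (-4.57 ± 0.05), F3 (-4.32 ± 0.04), Tgfb2 (-4.29 ± 0.06), Ccdc80 (-4.14 ± 0.07), Ankrd1 (-3.73 ± 0.06), Ptpn14 (-2.51 ± 0.03), Amotl2 (-2.33 ± 0.03) and Crim1 (-2.28 ± 0.08) were among them. Of 15 Hippo pathway components 9 fell and 4 rose (median -0.09; adjusted p = 0.0209, and adjusted p = 0.0806 with dim genes left out), with Amot (-3.42 ± 0.04), Vgll4 (-1.30 ± 0.10) and Wwc1 (-0.85 ± 0.03) lowest. All 16 actin and SRF genes fell (median -2.82; adjusted p = 6.9e-16), 12 by 2-fold or more, among them Myl9 (-4.56 ± 0.10) and Cnn1 (-4.39 ± 0.07). Fibroblast genes (7 of 10 lower, none higher; adjusted p = 0.000226), trophoblast genes (7 of 12 lower, 2 higher; adjusted p = 0.00471) and primitive endoderm genes (7 of 14 lower, 2 higher; adjusted p = 0.00822) fell as well. Among them were Col1a2 at -4.50 ± 0.08, Krt7 at -4.33 ± 0.07 and Col4a2 at -4.21 ± 0.05. The Actb 3′ minus 5′ value differed between these arms by 0.258, as given for array quality.

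In this medium without CHIR, 9 of 17 Wnt/beta-catenin targets were higher with YAP/TAZ siRNA, 6 of them by 2-fold or more, 3 lower and 5 not called. Sp5 rose by 2.13 ± 0.07, Cdx1 by 1.96 ± 0.07, Axin2 by 1.82 ± 0.04, Tnfrsf19 by 1.69 ± 0.03, Notum by 1.48 ± 0.03, Ccnd1 by 0.70 ± 0.03 and Lef1 by 0.51 ± 0.03. Dkk1 fell by 3.29 ± 0.06 and Sp8 by 0.87 ± 0.06. The list had an adjusted p = 0.0137, and adjusted p = 0.0544 with an estimated correlation. Of 18 Wnt pathway components, 7 rose and 9 fell (adjusted p = 0.323), with Porcn at 2.45 ± 0.06, Wls at -3.30 ± 0.04 and Tcf7l2 at -0.92 ± 0.03.

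Naive pluripotency genes rose with YAP/TAZ siRNA in 14 of 18 cases (15 adjusted over the list alone) and fell in 2 (adjusted p = 0.000132). Nr5a2 rose by 1.60 ± 0.03, Tfcp2l1 by 1.36 ± 0.02, Gbx2 by 1.13 ± 0.08, Dppa3 by 1.04 ± 0.03, Esrrb by 0.64 ± 0.02 and Nanog by 0.29 ± 0.02. The members that fell were the Krueppel-like factors Klf4 (-0.87 ± 0.03) and Klf5 (-0.28 ± 0.04). With the Actb 3′ minus 5′ value as a covariate Klf5 differed by -0.15 (adjusted p = 0.115). Fbxo15, among the 14 that rose, changed by 0.06 ± 0.02, and by 0.05 with that covariate (adjusted p = 0.266). Formative and primed genes fell in 9 of 12 cases and rose in 3 (adjusted p = 0.00471), with Fgf5 at -4.39 ± 0.12, Sall2 at -2.01 ± 0.07, Pou3f1 at -1.74 ± 0.04 and Otx2 at -1.24 ± 0.03. General pluripotency genes went both ways, 4 of 11 higher and 7 lower (adjusted p = 0.388), with Pou5f1 at 0.43 ± 0.03.

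A set of stress response genes fell with YAP/TAZ siRNA: 13 of 15 integrated stress and unfolded protein response genes were lower and 2 higher (median -0.78; adjusted p = 8.14e-07). Atf3 fell by 2.58 ± 0.08, Vldlr by 1.97 ± 0.04, Chac1 by 1.96 ± 0.06 and Trib3 by 1.54 ± 0.04. CHIR left this list without a common direction, 8 higher and 5 lower with a median of 0.09 and a mean of -0.06 (adjusted p = 0.823). Glycolysis genes rose, 10 of 11 higher and 1 lower (adjusted p = 0.00169), among them Pdk1 (1.04 ± 0.04) and Hk1 (0.73 ± 0.04), while the glucose transporter gene Slc2a1 fell by 1.16 ± 0.03. S phase genes rose in 12 of 15 cases (13 adjusted over the list alone) and fell in 2 (median 0.22; adjusted p = 0.0106), with Cdc45 at 0.67 ± 0.03. Of 14 p53 targets 11 fell and 3 rose (adjusted p = 0.00101), among them Perp (-2.24 ± 0.05), Pmaip1 (-2.12 ± 0.05) and the death receptor Fas (-1.84 ± 0.13). In all, 15 of 24 lists passed the threshold and 12 with an estimated correlation. LIF/STAT3 targets (8 of 11 lower, 3 higher) and cholesterol synthesis genes (8 of 12 lower, 2 higher) were past it only with the preset correlation, with adjusted p = 0.0209 and 0.0233, and adjusted p = 0.112 and 0.102 with an estimated correlation.

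**Figure D2:**
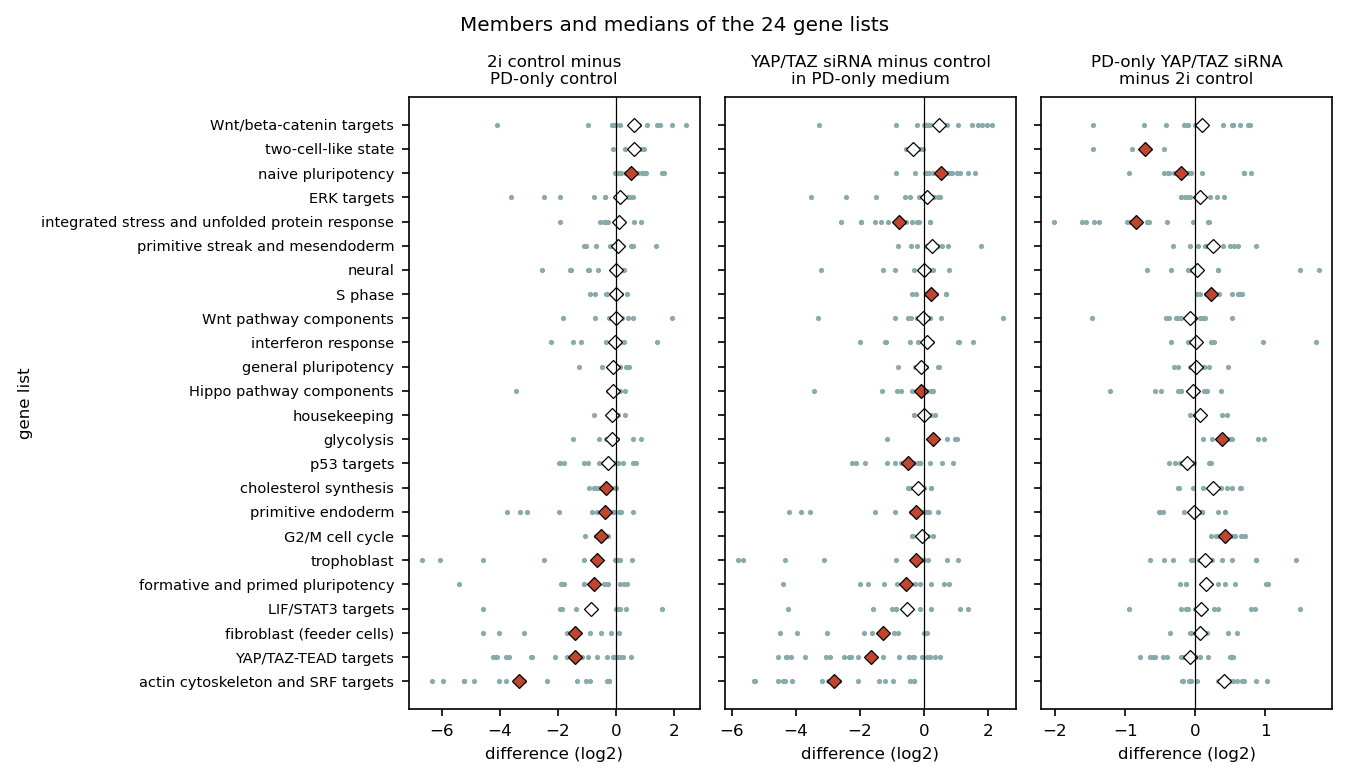
Log2 differences of the members (dots) and their median (diamonds) for the 24 gene lists in the 3 comparisons, ordered by the median in the first. Filled diamonds mark lists past an adjusted p of 0.05 with both the preset and an estimated correlation, 9, 12 and 6 lists from left to right; the actin and SRF list has medians of -3.33 and -2.82 in the first 2 panels.

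YAP/TAZ siRNA cells in PD-only medium still differed from control cells in 2i. Of 18193 genes, 8791 passed an adjusted p of 0.05, 4647 higher and 4144 lower with the siRNA, and 275 differed by 2-fold or more, 115 higher and 160 lower. Hbb-bh1 (3.55 ± 0.08), the homeobox gene Hesx1 (3.44 ± 0.09), Id1, a target of bone morphogenetic protein signalling (3.0 ± 0.06), Rimkla (2.52 ± 0.06) and Krtdap (2.45 ± 0.10) were highest among genes that met the naming rule. Fam13c (-2.92 ± 0.05), the activin antagonist Fst (-2.42 ± 0.04), Atp12a (-2.31 ± 0.11), Tsc22d3 (-2.27 ± 0.07) and Cpe (-2.08 ± 0.06) were lowest. The adjusted p of these 10 genes ranged from 4.37e-20 to 5.06e-13 with 8 and 7 arrays.

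G2/M, S phase and glycolysis genes stood higher in the YAP/TAZ siRNA arm than in 2i. These arms differ in both medium and siRNA, and the poly-A spikes stood lower by 0.533 in the siRNA arm. Within PD-only medium the siRNA did not raise the G2/M list, with 2 of 14 genes higher and 8 lower (median -0.08, camera's adjusted p = 0.129). Against 2i, all 14 G2/M genes were higher (median 0.42 and adjusted p = 9.96e-10), with Cdc20 at 0.71 ± 0.03 and Ube2c at 0.65 ± 0.03. So were 13 of 15 S phase genes, 14 adjusted over the list alone (adjusted p = 3.52e-06), with Ccne1 at 0.67 ± 0.04. All 11 glycolysis genes were higher too (median 0.38; adjusted p = 4.53e-08), with Pfkl at 0.98 ± 0.02 and Hk1 at 0.89 ± 0.04. Stress response genes stood lower, 12 of 15 with 2 higher (median -0.85; adjusted p = 6.54e-09), with Chac1 at -2.01 ± 0.06, Trib3 at -1.62 ± 0.04, Vldlr at -1.56 ± 0.04 and Ddit3 (CHOP) at -1.45 ± 0.03. All 5 two-cell-like genes were lower (median -0.72; adjusted p = 0.00015), with Zfp352 at -1.46 ± 0.04 and Tdpoz1 at -0.90 ± 0.07. Naive pluripotency genes were lower in 13 of 18 cases and higher in 4 (median -0.21; adjusted p = 0.00198). Klf4 differed by -0.95 ± 0.03, Klf5 by -0.44 ± 0.04, Esrrb by -0.39 ± 0.02 and Zfp42 by -0.28 ± 0.03. Gbx2 (0.80 ± 0.08), Dppa3 (0.69 ± 0.03) and Sox15 (0.69 ± 0.07) lay above their 2i level. The YAP/TAZ-TEAD targets (4 of 22 higher, 9 lower; median -0.07) and the Wnt/beta-catenin targets (8 of 17 higher, 6 lower; median 0.09) did not pass the test (adjusted p = 0.115 and 0.43). In all, 9 lists passed and 6 with an estimated correlation. Actin and SRF genes (9 of 16 higher, 4 lower), cholesterol synthesis genes (9 of 12 higher, 2 lower) and p53 targets (2 of 14 higher, 8 lower) were past the threshold with the preset correlation (adjusted p = 0.0236, 0.00642 and 0.046), and had adjusted p = 0.138, 0.0685 and 0.0953 with an estimated correlation.

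The responses to CHIR and to YAP/TAZ siRNA overlapped in 7535 genes called in both in the same direction, 4055 higher and 3480 lower. Against these stood 1034 called in opposite directions. Independent lists of these sizes would share 2026 higher and 1278 lower genes and hold 3226 in opposite directions. The fit with the Actb 3′ minus 5′ value as a covariate called 5555 genes in the same direction and 417 in opposite directions. Its correlation of the 2 responses over all genes was 0.871, against 0.868 without the covariate. The genes with the largest response in both, by the naming rule, were Car4, Prss23, S100a6, Acta1, Krt8, Krt18, Pmp22, Thbs1 and Tagln, all lower, and Nkx1-2, which was higher. Of genes that changed 2-fold or more in both, 795 went the same way, 190 higher and 605 lower, and 1 the opposite way, namely Atp12a (log2 1.03 with CHIR and -1.28 with the siRNA), which was below the level of the naming rule in both PD-only arms. Among opposite-direction genes above that level, the largest changes included Tubb3, a neuronal tubulin, at -0.97 ± 0.04 with CHIR and 0.79 ± 0.04 with the siRNA. The others were Rbm47 (-0.73 ± 0.03 and 0.77 ± 0.03), Pramel12 (-0.72 ± 0.04 and 0.75 ± 0.04), Tfap2c, a transcription factor of trophoblast and germ cells (-0.74 ± 0.06 and 0.71 ± 0.06), and the noncoding RNA Malat1 (0.77 ± 0.17 and -1.10 ± 0.17). Called in the other direction with CHIR were 2 of the 7 probe sets of Malat1, and with control siRNA 1 alone it differed by 0.46 (adjusted p = 0.101).

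Of the 1057 genes that CHIR changed 2-fold or more, 1030 (97.4%) moved the same way with YAP/TAZ siRNA, 795 of them by 2-fold or more; 13 moved the other way and 14 were not called. The siRNA response was a median 0.924 of the CHIR response (interquartile range 0.715 to 1.096), and 101 of the 1057 genes still differed 2-fold or more between the siRNA arm and 2i. For genes dim in both of these arms, such as Ankrd1 at 3.31 in 2i and 3.39 with the siRNA, the background pushes this ratio towards 1. The 307 genes higher in 2i had a median ratio of 0.790 (interquartile range 0.563 to 1.014), with 190 changed 2-fold or more by the siRNA and 42 still 2-fold different from 2i. The 750 lower genes, to which the limit of background applies, had a median ratio of 0.951 (0.799 to 1.107), with 605 and 59 such genes. Over all genes, which are not independent replicates, the differences correlated at r = 0.868 with a covariance of 0.297. The comparisons share the PD-only control arrays, so unchanged groups simulated against them gave r = 0.519 and a covariance of 0.002; with these controls split by siRNA, so that the comparisons shared none, r was 0.859 or 0.858 and the covariance 0.295 in both splits. The root mean square difference over genes was 0.583 between 2i control and PD-only control, 0.588 between YAP/TAZ siRNA and PD-only control, and 0.301 between YAP/TAZ siRNA and 2i control.

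**Figure D3:**
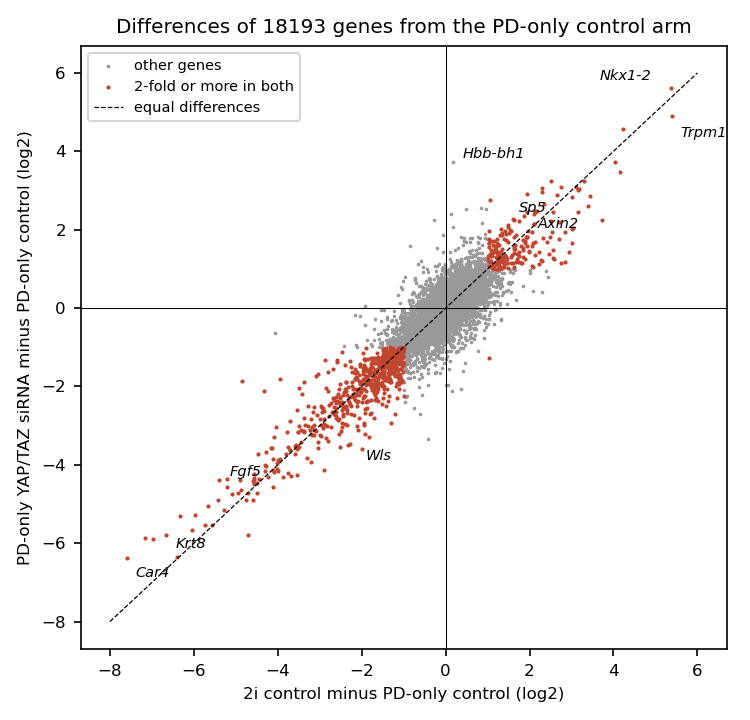
Log2 difference of each of 18193 genes from PD-only control, 2i control on the horizontal and PD-only YAP/TAZ siRNA on the vertical axis. Genes in red passed both thresholds in both comparisons, 795 in the same direction and 1 in the opposite one; the dashed line marks equal differences, and Hbb-bh1 lies high on the vertical axis alone.

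No gene was called different between siRNAs of one kind. In limma's test at an adjusted p of 0.05, 0 genes differed between the 2 YAP/TAZ mixes in PD-only medium (4 arrays each; 648 genes, 3.56%, had an unadjusted p under 0.05, where chance gives 5%), 0 between the control siRNAs in 2i (4 and 3 arrays; 1450 genes, 7.97%) and 0 between the control siRNAs in PD-only medium (4 and 3 arrays; 769 genes, 4.23%). The largest log2 differences were 0.51, 0.60 and 0.63. The effect of CHIR differed between the control siRNAs in 0 genes (949 genes, 5.22%, at an unadjusted p under 0.05). The SD of the difference between 2 arrays over genes had a median of 0.157 within an siRNA group and 0.156 between siRNA groups of the same arm. On simulated data the same test recovered 88.1%, 83.6% and 85.1% of genes changed by 0.5 on the log2 scale. Smaller differences than that were not tested for recovery.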

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

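The tests of RNA quality and of fibroblast genes were set up after the arms were seen to differ but before their own results were seen. The fits with controls split by siRNA and with each mix alone were planned. For these and for other splits of the arrays, what a result would mean was written after the results. The PD-only control arrays stood apart from both other arms at the actin and SRF, fibroblast and YAP/TAZ-TEAD lists, and their RNA quality sign differed in the same way. Within siRNA groups, the 1057 genes changed 2-fold or more by CHIR moved little with the Actb 3′ minus 5′ value. Scaled to the arm difference in that value, this trend makes up 0.229% of their arm difference (95% interval -0.646% to 1.1%). The value was at most 0.75 in PD-only control and at least 0.87 in 2i control, so the trend is carried beyond its range. Actb is also on the actin and SRF list, so the value may not be independent of the pattern. The Gapdh 3′ minus 5′ value was lower in PD-only control as well, by 0.063 than in 2i control and by 0.058 than with YAP/TAZ siRNA. With the middle Gapdh probe set in place of the 5′ one, the differences had the other sign. The trend, carried beyond its range, does not decide on RNA quality as the cause. Fibroblasts in the PD-only control cultures stay open. Of 20 measured genes on a second list of abundant fibroblast genes, 16 (80%) were higher in PD-only control, 10 by 2-fold or more. The smallest of the 16 rises was 0.15, for Col6a2, and Fap and Mgp, dim in both arms, were not called. But Fn1 and Fstl1 were higher in 2i, by 0.67 and 0.60, and Krt8 and Krt18 mark simple epithelia. The withdrawal of CHIR itself, which the design names, may also have changed the ES cells. But the YAP/TAZ siRNA arm had the same withdrawal, so withdrawal alone does not set PD-only control apart from that arm. The root mean square difference of the YAP/TAZ siRNA arm was 0.588 from PD-only control and 0.301 from 2i control.

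Noise in the shared PD-only control arrays adds little to the agreement of the CHIR and YAP/TAZ siRNA responses. Unchanged groups simulated against the shared controls gave a covariance over genes of 0.002, against 0.297 for the measured responses. With no shared array the covariance was 0.295, but all these controls came from the same PD-only control arm. Anything peculiar to that arm as a whole could give this agreement, which the split of the controls by siRNA cannot test. Splits of the arrays do not test this agreement, but argue against random labels behind the count of each comparison. With the real split included, 1 of 100 drawn splits called as many genes for CHIR (10559, highest other split 8246). It was 1 of 100 for YAP/TAZ siRNA (11250, highest other 8719) and 1 of 100 for YAP/TAZ siRNA against 2i (8791, highest other 5960). The other splits had a median of 0 calls. A batch that follows the arms would give the same result. In PD-only medium, the siRNA mixes against YAP and TAZ moved 1030 of the 1057 genes changed 2-fold or more by CHIR the same way. Whether this came through the loss of YAP and TAZ or through a property that both mixes share, and by what route, was not tested.

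The lower stress response genes after YAP/TAZ siRNA appeared with both mixes, with list medians of -0.79 and -0.77 against PD-only control, which argues against an off-target effect of 1 mix. The within-group trend with the Actb 3′ minus 5′ value makes up 2.8% of the difference in the list mean (95% interval -1.18% to 6.79%). That value was at most 0.75 in PD-only control and at least 0.88 with YAP/TAZ siRNA. The trend is thus carried beyond its range here too and does not decide on RNA quality. The list was lower against 2i as well, where the Actb value differed by 0.009. An effect of the loss of YAP and TAZ, or of a sequence-independent property that both mixes share and the control siRNAs lack, may remain, and neither was tested.

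For the siRNAs of one kind the count of splits decides nothing, because any split gives at least the 0 genes called in the real one. All 35 splits did so for the 8 YAP/TAZ siRNA arrays (highest other 2), for the control arrays in 2i (highest other 1) and for those in PD-only medium (highest other 3). At an unadjusted p under 0.05, the split by mix had the fewest genes of the 35, 648, against up to 1548 in another split. For the control siRNAs, 3 of 35 splits gave as many such genes as the real one in 2i (1450) and 13 of 35 in PD-only medium (769).

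Single arrays far from the other 3 of their group were found in 31 of 580 tests (5.3%), close to the 5% that chance gives, and are given as values only. Malat1 was 12.08 in YAP/TAZ mix 1 replicate D against 10.72 to 10.78 in the others, Col1a1 was 4.69 in mix 2 replicate B against 5.31 to 5.32, and Hesx1 was 3.96 in 2i control 1 replicate B against 4.32 to 4.33. Other arrays of 2i control 1 were replicate C for Wwtr1 (10.07), Car4 (3.70), Ddit3 (8.99) and the Actb 3′ minus middle value (0.86), and replicate D for Epp13 (9.95), Vgll4 (7.28), Dusp5 (6.61) and the hybridisation spikes (11.244). In PD-only control 1 they were replicate A for Trh (7.98) and Ddit3 (8.73), and replicate B for Acta1 (13.05), Wwc1 (9.71), Gata3 (8.09) and the array median (5.54). In YAP/TAZ mix 1 they were replicate A for Icam1 (8.58, with the others at 8.57), replicate B for Prss23 (3.64), Fbxo15 (12.55), Sox15 (7.81) and the array median (5.51), and replicate C for Nr5a2 (10.46) and the Gapdh 3′ minus middle value (0.17). In mix 2 they were replicate A for Fos (5.57), replicate B for Postn (4.86) and Pdk1 (10.97), replicate C for Ddx58 (9.13), and replicate D for Car4 (5.44), Hmgcs1 (11.62) and the array median (5.51).

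Signals also appeared in the 10092 probe sets without a single gene symbol, which the gene tests leave out: 176 differed 2-fold or more with CHIR, 173 with YAP/TAZ siRNA and 69 between YAP/TAZ siRNA and 2i control, or 1.7%, 1.7% and 0.7% of them, against 4.9%, 5.3% and 1.3% of probe sets with 1 symbol.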

How the results depend on the processing

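The RNA quality covariate was chosen after the data were seen; the other 21 settings and the 22 fits without 1 array were planned. The 6 counts of called genes stayed within 1.5 times their main value in every setting, except that an intensity trend with robust variance called 2 genes between the control siRNAs in 2i and 1 in PD-only medium, where the main count was 0; the cause was not tested. With 1 array left out, CHIR called 10120 to 10570 genes, YAP/TAZ siRNA 10763 to 11381, and YAP/TAZ siRNA against 2i 8511 to 8797. With the RNA quality covariate, opposite-direction calls fell from 1034 to 417 and same-direction calls from 7535 to 5555. That fit called 7796 genes for CHIR and 8204 for YAP/TAZ siRNA, and the cause was not tested. At 2-fold or more it called 1103 and 1195 genes, against 1057 and 1158 without the covariate. The correlation of the 2 responses over genes was 0.871, against 0.868. The Actb value did not overlap between PD-only control and the other arms, so this fit does not decide on RNA quality. Counts of shared calls were 795 same and 1 opposite with a 2-fold threshold, which asks for more by construction. The 14 lists past the threshold with CHIR became 9 with an estimated correlation; the cause was not tested. Whether replicate letters share more than a name was not tested against chance. Of 51 same-letter pairs of arrays across groups, 2 correlated above 0.1 in their deviations from group means. The median correlation was 0.002, against -0.002 for pairs with different letters. By these correlations, 9 of 22 arrays were closest to an array of their own letter among the arrays of other groups. With the replicate block 10542, 11261 and 8714 genes were called in the 3 comparisons. The same block left 11 of 14 lists past the threshold with CHIR, without the neural (adjusted p = 0.0669), two-cell-like (0.0502) and LIF/STAT3 (0.0518) lists, and p53 targets had adjusted p = 0.051 against 2i. The Gapdh 3′ signal minus the middle probe set in place of the 5′ one turned the sign of the difference from PD-only control from 0.063 to -0.014 in 2i and from 0.058 to -0.032 with YAP/TAZ siRNA; the cause was not tested. Acta2 between YAP/TAZ siRNA and 2i turned from 0.70 to -0.21 without cross-hybridising probe sets, which replace its probe set by a dimmer one. Of 411 values of named genes, 373 kept their side of the threshold in every setting. With 1 array left out, 5 lists with an adjusted p of 0.0436 to 0.0528 crossed the threshold: with CHIR, the neural list was lost without any 1 of 12 arrays (highest adjusted p = 0.0648), the LIF/STAT3 list without any 1 of 6 (highest 0.0557) and the two-cell-like list without 2i control 1 replicate C (0.0579); p53 targets against 2i were lost without any 1 of 6 (highest 0.0719), and the two-cell-like list with YAP/TAZ siRNA was gained without any 1 of 6 (lowest 0.0422). With YAP/TAZ siRNA the two-cell-like list also passed with the mean of all probe sets of a gene (adjusted p = 0.0407), without cross-hybridising probe sets (0.0486), with median-centred arrays (0.0483) and with only the groups of the contrast (0.0369), and the G2/M list with a repeated quantile normalization (0.0463). The primitive streak list passed against 2i with the mean of all probe sets of a gene (0.0398). The Wnt/beta-catenin list had adjusted p of 0.0107 to 0.0642 with CHIR and 0.00465 to 0.0544 with YAP/TAZ siRNA over 34 settings. A further scaling of the arrays moved the median of all genes by at most 0.03. Camera with the random siRNA block was not run. Genes dim in 1 arm are limited by signal over background, and 11621 of 18193 passed the filter on dim genes.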

Other observations

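No test in this part was chosen after its result was seen. Single members of the LIF/STAT3 and ERK target lists were higher in PD-only control than in either other arm, while others were lower. Socs3 had log2 differences of -4.58 ± 0.08 with CHIR and -4.24 ± 0.08 with YAP/TAZ siRNA, Fos of -3.60 ± 0.09 and -3.52 ± 0.09, Phlda1 of -2.47 ± 0.06 and -2.45 ± 0.06, Junb of -1.86 ± 0.10 and -1.59 ± 0.10, and Dusp5 of -1.92 ± 0.04 and -1.51 ± 0.04. ERK targets as a list went both ways, with 6 of 14 higher and 6 lower in both comparisons (adjusted p = 0.451 with CHIR, where the median was 0.12 and the mean -0.51, and 0.401 with YAP/TAZ siRNA), and had an adjusted p = 0.685 between YAP/TAZ siRNA and 2i. Icam1 fell with CHIR by 1.93 ± 0.04 and stood 1.49 ± 0.03 higher with YAP/TAZ siRNA than in 2i. Among interferon response genes, Cxcl10 fell in both (-2.22 ± 0.08 and -1.99 ± 0.08), Ddx58 rose by 1.40 ± 0.03 with CHIR, and Oas1a rose by 1.53 ± 0.03 with YAP/TAZ siRNA, where it stood 1.72 ± 0.03 above 2i, as did Rsad2 by 0.96 ± 0.06; the list did not pass in any comparison (adjusted p = 0.401, 0.989 and 0.441).

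Single lineage genes also held large changes. Sox11 fell with CHIR by 2.53 ± 0.05 and with YAP/TAZ siRNA by 3.22 ± 0.05, and Map2 by 1.59 ± 0.07 and 1.27 ± 0.07, while Pax6 was lower in 2i than in PD-only control (-1.55 ± 0.05) and higher with YAP/TAZ siRNA than in 2i (1.49 ± 0.05); the neural list, past the threshold with CHIR at the preset correlation only, had an adjusted p = 0.195 with YAP/TAZ siRNA and 0.561 against 2i. Lefty2, a Nodal antagonist, rose with CHIR by 1.38 ± 0.04 and with YAP/TAZ siRNA by 1.77 ± 0.04, and Eomes, which is on the trophoblast list too, fell with CHIR by 1.10 ± 0.06 and stood 0.87 ± 0.06 higher with YAP/TAZ siRNA than in 2i; the primitive streak list did not pass (adjusted p = 0.823, 0.174 and 0.0707). Housekeeping genes did not pass as a list (adjusted p = 0.261, 0.945 and 0.2), although Gusb fell with CHIR by 0.75 ± 0.04. Between YAP/TAZ siRNA and 2i, the lists of general pluripotency (adjusted p = 0.709), formative and primed pluripotency (0.0985), Wnt pathway components (0.0708), Hippo components (0.186), primitive endoderm (0.569), trophoblast (0.305), fibroblast (0.561) and LIF/STAT3 targets (0.569) did not pass. With YAP/TAZ siRNA against PD-only control, G2/M genes (adjusted p = 0.129) and two-cell-like genes (0.0528) did not pass, nor did glycolysis (0.0675) or S phase genes (0.429) with CHIR.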
